A study of Rattus norvegicus with 7 samples.

How the data were processed

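RNA from whole brain was labelled with biotin and hybridized to 1-colour arrays, 1 rat per array, per the labels. The series' design text states that rats were hybridized separately and that an NP array was dropped by the authors in quality control, so replicates are separate rats. Groups and replicate numbers were taken from the sample titles. The deposited scanner tables, per the file headers, give for each spot the mean intensity, the median intensity of its local background, a background-subtracted intensity, a scaled intensity and a quality flag. The subtracted value equalled spot minus background on every transcript probe, within 0.01. The authors also deposited a table of log2 values, whose method is not given in the sources used here. Those columns followed the log2 of the scaled intensity of the same array (r of 0.9986 or higher), and their medians lay between -0.07 and 0.05. Outlier-flagged spots are blank there, direction and scale match the scanner values, and a further adjustment between arrays stays unknown. The software of the scanner and the genome build are not given in the sources used here.

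Values were made with limma 3.58.1 in R 4.3.3: normexp background correction with offset 50 on spot and background intensities, then quantile normalization over transcript probes. Control spots (240 positive, 256 negative) were left out after the background step. Spots flagged masked, irregular or contaminated were set to missing, and saturated spots were kept. A probe counted as above background on an array when it carried neither an outlier flag nor the near-background flag. The 29008 probes above background on at least 3 of the 7 arrays, whatever their group, were kept, and 29003 could be fitted. Of these, 21770 lay above background on all 7 arrays. A first run left the local background out of the correction through a coding error, and it was looked at before the error was found. It called 75 probes, all of them among the 84 of the corrected run, and is kept as an alternative.

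Probe accessions without versions were matched to RefSeq transcripts of the GRCr8 table, which was used only for names and gene order since the files name no build. This named 7207 of 33849 probes, for 6046 genes, and 5677 genes were tested. A gene was represented by its probe with the highest mean over the 7 arrays. Probes without a match keep their probe ID.

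The lines were compared with lmFit and eBayes, with no block, and p-values were adjusted by Benjamini-Hochberg. A call is an adjusted p under 0.05, and all differences are P minus NP in log2. Gene lists were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, with missing spots filled by the probe's mean. Old list symbols were matched through the table's synonyms. Where a probe was not above background on any array of a group, the fold is a lower bound: the bright group's mean against the mean of, per array, the higher of the dim probe's value and the lowest signal among probes above background. This was so for 5 of the 84 called probes, and no fold of these is printed. Chromosomes were tested with Fisher's exact test.

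Before the data were examined, the tests, the gene lists, the alternatives and the genes to be named were fixed. Named are, with 1 probe per gene, up to 12 called genes per direction by size with no overlap between the 4 P and 3 NP values and above background on every array of a line. Where fewer than 5 passed in a direction, the 5 with the smallest p were given as values. From each list up to 3 called members were named, or the member with the smallest p, and all measured genes of the list earlier linked to alcohol preference. Some genes that this covers are not reported here. Alternatives were other background corrections, scalings, filters and variance models, the authors' values, replicate number or scan date as a block, array weights, a plain test per probe, and each array left out. Alternatives on single scan dates, on pairs of P arrays left out and on scan date as a random block were added after seeing the data.

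The fit was tested on simulated data with the mean and spread of the 29003 probes and 4 against 3 arrays, with 200 changed probes in each of 5 runs. For the P against NP comparison it recovered 13.5% of changes of 0.5 on the log2 scale, 89% of changes of 1 and 100% of changes of 2, and 6.64% of calls were false. Small differences would therefore mostly be missed. The share of false calls holds for data simulated in this way. It may not carry over to arrays with the scan dates and the differences among P rats given below. Figures were drawn with matplotlib 3.10.9.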

Results

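RNA from the whole brain of adult male rats of the alcohol-preferring (P) and non-preferring (NP) lines was measured on 1-colour oligonucleotide arrays, with 1 array per rat. The lines were bred selectively for high and low voluntary alcohol drinking, and the rats had not been given alcohol. The data hold 4 P rats (replicates 1 to 4) and 3 NP rats (replicates 2 to 4), housed in pairs. Each array carried 33849 transcript probes, of which 26361 to 28084 lay above background on all arrays but NP 4, where 29091 did. In the P rats 77.9% to 81.6% of probes were above background, and in the NP rats 81.5% to 85.9%. The number of arrays limits the precision. The arrays had been scanned on 3 dates: NP 2, NP 3, P 1 and P 2 on date 1, NP 4 on date 2, and P 3 and P 4 on date 3.

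The comparison of the lines asks which transcripts differ in the brain before any exposure to alcohol. Bnip3, a mitochondrial protein of the autophagy and cell death pathways, was higher in P by 3.15 ± 0.19 on the log2 scale (difference ± SE, adjusted p = 4.75e-05). Lamp1, a major lysosomal membrane protein, was higher by 2.56 ± 0.17 (adjusted p = 6.06e-05). Fth1, the heavy chain of the iron store ferritin, was higher by 2.32 ± 0.22 (adjusted p = 0.000642), and Mmadhc, which acts in intracellular vitamin B12 handling, by 2.32 ± 0.18 (adjusted p = 0.000139). Cd151, a tetraspanin of the cell surface, was lower in P by -2.40 ± 0.19 (adjusted p = 0.000194), and Ppat, which catalyses the committed step of purine synthesis, by -1.46 ± 0.11 (adjusted p = 0.000124). For each of these 6 genes no P value overlapped an NP value, which the rule for naming required. Their calls held whichever of the 7 arrays was left out. For none of these 6 genes was a second probe of the same transcript tested, so each rests on 1 probe. The 4 called probes that had a second probe were not matched by it, as given below. In a plain equal-variance test per probe, Bnip3, Lamp1 and Ppat kept the call. Fth1 (adjusted p = 0.153), Mmadhc (adjusted p = 0.0684) and Cd151 (adjusted p = 0.0844) missed the threshold in that test.

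In all, 84 of 29003 tested probes differed between the lines by limma at an adjusted p under 0.05, 39 higher and 45 lower in P. Of these, 67 differed at least 2-fold, 31 higher and 36 lower. The median size of a called difference was 1.32 on the log2 scale. For all 82 called probes with 7 values the P and NP values did not overlap. Over all 27255 tested probes with 7 values, groups did not overlap for 13.3%, where chance gives 5.71%. Only 13 of the 84 called probes could be given a gene name, and 71 could not, so the list of genes is a small part of what differed. At an unadjusted p under 0.05 there were 3348 probes, where 1450 would be given by chance. Scan date was only partly shared by the lines, and the P rats differed among themselves, as given below. So neither excess over chance is a count of differences due to the line.

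Bnip3 read 10.08 ± 0.18 (SD, n = 4) in P and 6.93 ± 0.43 (SD, n = 3) in NP, in log2 normalized signal. Lamp1 read 11.11 ± 0.31 (SD, n = 4) against 8.55 ± 0.13 (SD, n = 3). Cd151 read 6.48 ± 0.34 (SD, n = 4) in P, above background on 3 of 4 arrays, against 8.88 ± 0.23 (SD, n = 3) in NP. Ppat read 6.38 ± 0.08 (SD, n = 4) in P, above background on 2 of 4 arrays, against 7.83 ± 0.03 (SD, n = 3). Fth1 read 9.30 ± 0.43 (SD, n = 4) in P against 6.98 ± 0.24 (SD, n = 3) in NP. Mmadhc read 8.68 ± 0.33 (SD, n = 4) against 6.36 ± 0.14 (SD, n = 3). Both were above background on every array. Negative control spots had medians of 6.19 to 6.33 before normalization between arrays, so these NP signals were low, most so for Mmadhc. Fth1 has many processed copies in mammalian genomes, and its probe was not checked against them. Also higher in P were Adprhl1, an ADP-ribosylhydrolase-like protein, by 1.30 ± 0.15 (adjusted p = 0.00263), Pard3, a cell polarity scaffold, by 1.25 ± 0.21 (adjusted p = 0.043), and Psmb8, an interferon-inducible subunit of the immunoproteasome, by 0.95 ± 0.14 (adjusted p = 0.0153). Pard3 passed in 1 and Psmb8 in 3 of the 7 fits that left out 1 array, with adjusted p up to 0.338 and 0.134. Neither passed in the values as processed by the authors (adjusted p = 0.083 for Pard3 and 0.061 for Psmb8), where Cd151 also missed the threshold (log2 difference -3.67, adjusted p = 0.0567).

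**Figure D1:**
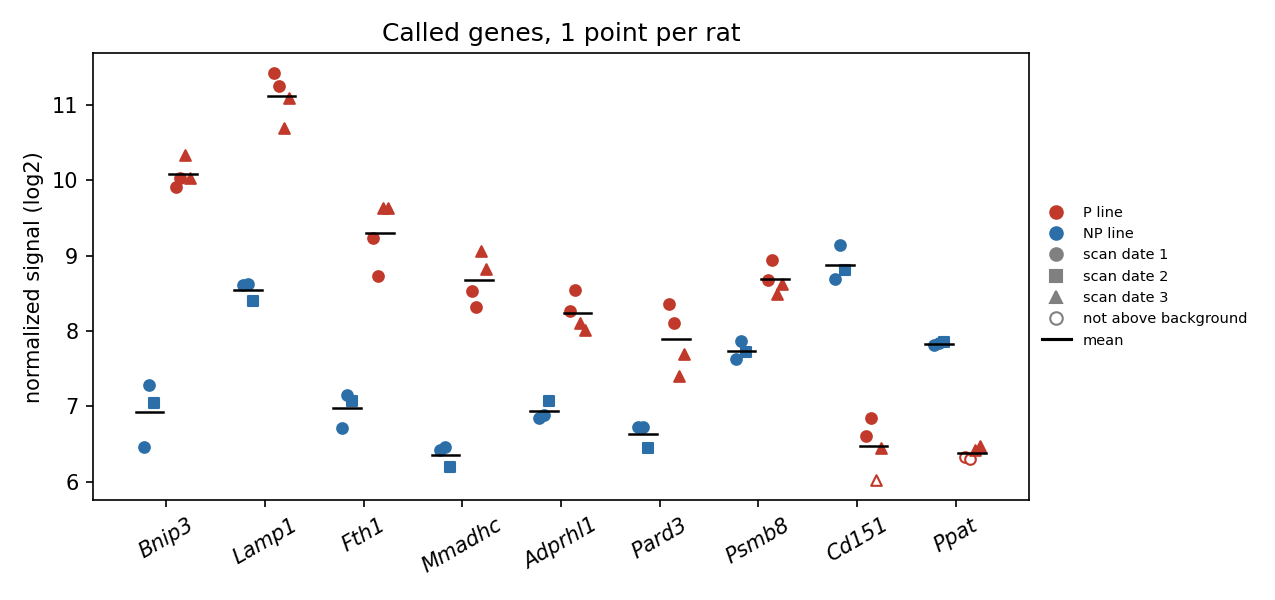
Log2 normalized signal (vertical axis) of the 9 genes named by the rule for called genes, with 1 point per rat, colour for line, shape for scan date, open points for spots not above background and a bar for the group mean. Lamp1 shows the P rats at 10.69 or above and the NP rats at 8.63 or below.

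Fewer than 5 genes passed in the lower direction, so the next by p are given as values only. The P minus NP differences were -0.70 ± 0.13 for Cd302 (adjusted p = 0.0847), -0.65 ± 0.12 for Golph3l (adjusted p = 0.093) and -0.59 ± 0.12 for Pter (adjusted p = 0.103). With scan date as a block, where the line term rests on the arrays of date 1, each of them was called. The values there were -0.83 for Cd302 (adjusted p = 0.0117), -0.75 for Golph3l (adjusted p = 0.0227) and -0.62 for Pter (adjusted p = 0.0361).

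Further called probes fell outside the naming rule and were chosen after their values were seen. For 3 genes the called probe was not the brighter of a pair. Probe GE18004 of Tmed9, a protein of vesicle traffic, was higher in P by 3.71 ± 0.24 (adjusted p = 6.06e-05), while GE1213656 of the same gene differed by 0.00 ± 0.11 (p by limma 0.986). Probe GE1135776 of Timm10, a mitochondrial import chaperone, was lower in P by -1.60 ± 0.19 (adjusted p = 0.00423), while GE13389 differed by -0.11 ± 0.17. Probe GE13432 of Ppp2r2d, a regulatory subunit of protein phosphatase 2A, was higher by 1.22 ± 0.18 (adjusted p = 0.0223), while GE1101572 differed by 0.02 ± 0.16. In NP probe GE13432 was above background on 1 of 3 arrays. Its call held in 3 of the 7 fits that left out 1 array (adjusted p up to 0.202), and it missed the threshold in the authors' values (adjusted p = 0.0856), where the Timm10 probe did so too (adjusted p = 0.0743). Among unnamed probes, GE1153031 (2.75 ± 0.12) and GE14932 (2.95 ± 0.14) had the smallest p of those higher in P, and GE1238638 (-2.54 ± 0.13) and GE1223711 (-1.85 ± 0.12) of those lower. GE1238638 was above background on 1 of 4 P arrays.

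**Figure D2:**
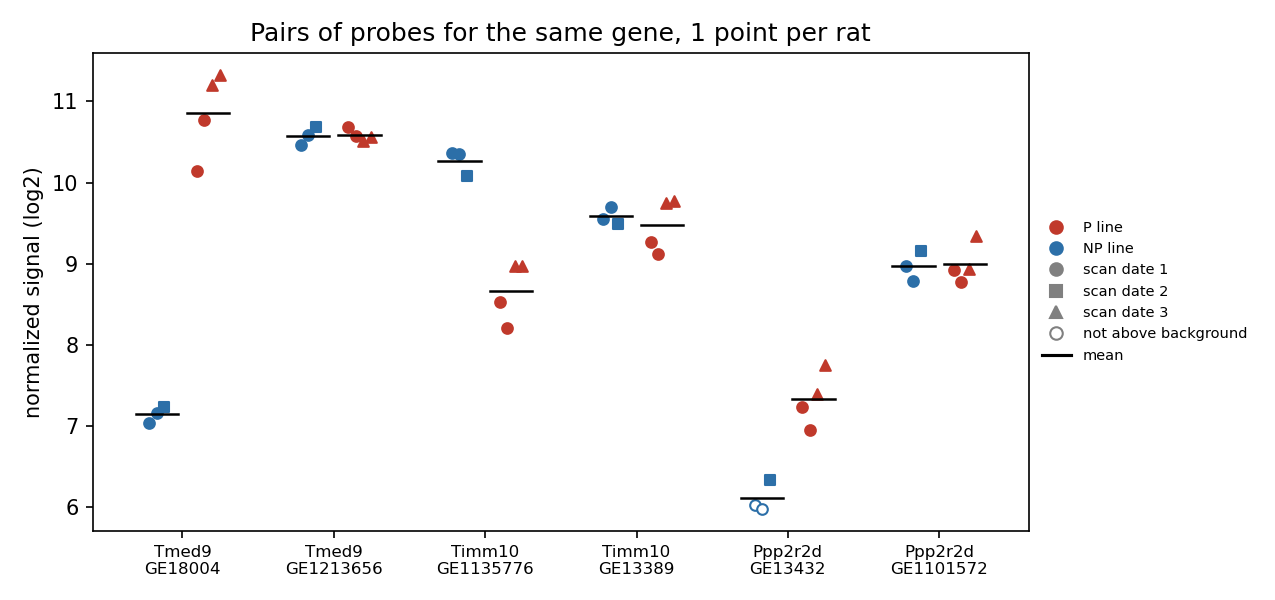
Log2 normalized signal (vertical axis) of pairs of probes for Tmed9, Timm10 and Ppp2r2d, with 1 point per rat, colour for line, shape for scan date, open points for spots not above background and a bar for the group mean. In each pair 1 probe separates the lines and the other does not, for example 3.71 against 0.00 for Tmed9.

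Scan date held both lines on date 1 only, with 2 arrays of each line. Within date 1, 83 of the 84 called probes were called, on arrays that are part of the full comparison, and Bnip3, Lamp1 and Cd151 differed by 3.10, 2.71 and -2.19. In all, 1870 probes were called within date 1, and 1660 in the fit with scan date as a block, whose line term rests on those same 4 arrays, so the date is not separated here from the pair P 1 and P 2. In the authors' processed values 36 probes were called within date 1, or 1078 with a variance prior that follows intensity. The blocked fit put 28.9% of its calls higher in P, against 46.4% without the block.

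The P rats did not form 1 cluster. Rats P 1 and P 2 differed from P 3 and P 4 at 4003 probes (1824 higher, 2179 lower), and 9 of the 84 line calls were among them. The count of 4003 fell to 1 with plain background subtraction and to 2 in the authors' processed values. With a variance prior that follows intensity it was 3549 and 3295 there. Leaving P 1 and P 2 out gave 189 calls between the lines, 80 of them among the 84, and leaving P 3 and P 4 out gave 3318.

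**Figure D3:**
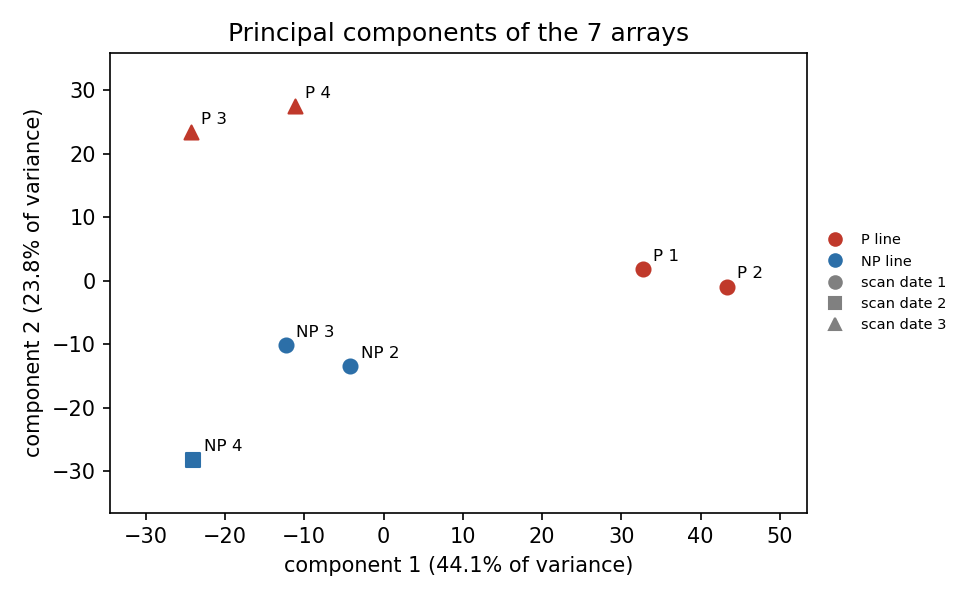
Principal components of the 7 arrays over probes with 7 values (axes in log2 units), with 1 point per rat, colour for line and shape for scan date. The first component, 44.1% of the variance, sets P 1 and P 2 apart from the other arrays.

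The 31 gene lists fixed beforehand asked whether transmitter systems, alcohol metabolism, stress, immune and cell type genes differ together. Of 512 tested list genes, 1 was called, Psmb8. No list passed limma's camera test (smallest adjusted p = 0.195, and 0.932 with an estimated correlation), and 1 list had an unadjusted p under 0.05. With fry, 0 lists moved one way on balance. Its test for change in either direction, which does not compare a list with other genes, passed for 3 lists. They were glucocorticoid-responsive genes (fry adjusted p = 0.00852), opioid peptides and receptors (0.0425) and MHC and interferon response (0.0425).

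None of the 10 tested genes of alcohol and acetaldehyde metabolism passed, and the smallest p was that of Cat, catalase (0.45 ± 0.22, adjusted p = 0.455). Within scan date 1 Cat differed by -0.02 (adjusted p = 0.955). Between P 1 and P 2 and the other P rats, P 3 and P 4, it differed by -0.66 ± 0.16 (adjusted p = 0.0242). Of the 8 genes earlier linked to alcohol preference in selectively bred rats, 4 had a named probe, 3 were tested and none passed over all 7 arrays. Npy differed by -0.32 ± 0.23 (adjusted p = 0.581) and Crh by -0.07 ± 0.13 (adjusted p = 0.845). Within scan date 1 Npy differed by -0.62 (adjusted p = 0.0823). In the fit without P 3 and P 4, added after seeing the data, it was called (-0.68, adjusted p = 0.0346). Its values in P 1 and P 2 differed from those in P 3 and P 4 by -0.71 ± 0.20 (adjusted p = 0.0448). Npy read 9.39 ± 0.49 (SD, n = 4) in P and 9.72 ± 0.11 (SD, n = 3) in NP.

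Of 22 GABA genes none passed over all probes and 2 did adjusted over the list alone, with the receptor subunits Gabra5 at -0.42 ± 0.10 and Gabrd at 0.55 ± 0.14. Among 34 genes of cAMP and protein kinase signalling, Camk2b (0.71 ± 0.13, adjusted p = 0.0912) passed adjusted over the list alone. Among 12 glucocorticoid-responsive genes, Nr3c1, the glucocorticoid receptor (-0.54 ± 0.12, adjusted p = 0.146), and Cdkn1a (-0.54 ± 0.12) did so. Among 21 genes of MHC and interferon response, Psmb8 was higher, and the class II gene RT1-Db1 (-1.10 ± 0.22) passed with it over the list alone. Cox7a2 of 31 oxidative phosphorylation genes (-0.56 ± 0.12) did so too. None of 27 glutamate, 20 catecholamine, 15 serotonin, 7 opioid, 36 neuropeptide, 5 endocannabinoid, 36 antioxidant, 54 channel, 20 immediate early or 10 clock genes passed, over all probes or adjusted over the list alone. The smallest p in those lists were those of Grik5 (0.47 ± 0.14), Dbh (0.38 ± 0.13), Htr1b (0.38 ± 0.13), Oprm1 (0.22 ± 0.11), Cartpt (-0.51 ± 0.18), Abhd12 (0.18 ± 0.14), Txn1 (-0.37 ± 0.14), Scn3a (-0.52 ± 0.12), Nr4a2 (-0.57 ± 0.19) and Bhlhe40 (0.33 ± 0.15), in that order. These are the values over all 7 arrays. With scan date as a block, calls appeared in 6 of these lists: Grik5 (0.65) for glutamate, Adra2c (0.68) for catecholamines, Slc6a4 (-1.05) for serotonin, Tac1 (-0.62) and Cartpt (-0.74) for neuropeptides, Glo1 (-0.56), Prdx1 (-0.98), Gstm3 (-0.76) and Gsta1 (-0.85) for antioxidants, and Scn3b (-0.66) and Cacna2d1 (-0.78) for channels. In the lists before them calls with the block included Ppp3cb (-0.95), Gng7 (0.66), Camk2b (0.64), Psmb8 (1.06) and RT1-Db1 (-1.43). The adjusted p of these calls lay between 0.00922 and 0.0493, and those without a value over all 7 arrays here were named after their values were seen.

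No member of the 13 lists of cell type and region markers was called in the comparison of all 7 arrays. Of the 146 marker genes tested, 18 were called within date 1, 7 higher and 11 lower in P, in 7 of the lists. With scan date as a block 15 were, 4 higher and 11 lower, also in 7 lists. That is 12.3% and 10.3% of the markers, where 6.34% and 5.58% of all genes were called. The marker lists as a whole did not pass camera in either (smallest adjusted p = 0.37 within date 1 and 0.309 with the block). Over all 7 arrays only Slc22a6, a meningeal marker (0.72 ± 0.18, adjusted p = 0.244), passed adjusted over the list alone. The members with the smallest p there were Uchl1 (0.37 ± 0.17) for neurons, Aqp4 (-0.45 ± 0.19) for astrocytes, Mog (-0.45 ± 0.16, 2 P and 3 NP values) for oligodendrocytes, Aif1 (-0.81 ± 0.24) for microglia, Kcne2 (-0.32 ± 0.12) for choroid plexus, Asmt (-0.57 ± 0.19) for pituitary and pineal, and Alas2 (0.38 ± 0.25) for erythroid cells. For the regions they were Pcp4 (-0.40 ± 0.15) for cerebellum, Adora2a (0.42 ± 0.18) for striatum, Wfs1 (0.20 ± 0.17) for cortex and hippocampus, Lhx5 (0.27 ± 0.13) for olfactory bulb and Dbh for hypothalamus and brainstem.

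Of 33 ribosomal protein genes none was called, with a list median of -0.11 and camera's adjusted p = 0.195; Rps3a had the smallest p (-0.64 ± 0.23). Within scan date 1, 10 of the 33 were called lower in P and none was called higher, with a median of -0.28 (camera adjusted p = 3.69e-07, adjusted p = 0.985 with an estimated correlation). With scan date as a block the median was also -0.28 (camera adjusted p = 9.65e-08, adjusted p = 0.978 with an estimated correlation). For oxidative phosphorylation 7 of 31 genes were called lower within date 1, with a median of -0.25 (camera adjusted p = 0.00111, adjusted p = 0.985 with an estimated correlation), and 6 of 31 with the block (adjusted p = 0.00104, and 0.978 with an estimated correlation). Immediate early genes had a median of 0.28 within date 1 (camera adjusted p = 0.0561) and with the block (adjusted p = 0.0336, and 0.978 with an estimated correlation). Over all 7 arrays their median was 0.02, while camera ranked them lower in P (adjusted p = 0.778). Without P 1 and P 2 their median was -0.21 (camera adjusted p = 0.00589, adjusted p = 0.963 with an estimated correlation), the opposite direction. These 3 lists also passed camera between P 1 and P 2 and the other P rats, P 3 and P 4, and 0 lists did so with an estimated correlation (adjusted p = 0.972 for each of the 3).

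A quantitative trait locus for alcohol preference of these lines was mapped to chromosome 4, so called genes were counted by chromosome in the order of the GRCr8 annotation. None of the 10 genes called by their brightest probe lay among the 356 tested genes of chromosome 4, of 5677 genes placed. With so few called genes, none on that chromosome is a likely outcome by chance alone. The 71 called probes without a gene name could not be placed. The count therefore does not speak for or against that locus. Chromosome 1 held 4 of 755 (Bnip3, Cd151 and Fth1 among them, adjusted p = 0.353 by Fisher's exact test, two-sided) and chromosome 16 held 2 of 162 (Adprhl1 and Lamp1, adjusted p = 0.353). No chromosome of 21 passed.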

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

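The tests of the number of calls by splits, of second probes and of gene neighbours, and the size test of the scan date pattern and its marker list test, were chosen after the result was seen; the other tests below were chosen before.

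The value of Slc22a6 in rat P 3 (8.15 on the log2 scale) lay below those of the other P rats (8.44 to 8.47). It was 1 of 57 sets of P values tested for a lone distant sample, and about 2.8 would be flagged by chance. The NP group, with 3 rats, was not tested.

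Over the 35 splits of the 7 arrays into 3 and 4, 2 gave at least the 84 calls of the real split, so chance cannot be excluded for that count. The highest other split, with 293 calls, set NP 2, P 1 and P 2 against the rest and points to a structure of the arrays rather than the line. It joins 3 of the 4 arrays of scan date 1, while the like split with NP 3 in place of NP 2 gave 0 calls. The split of the 4 arrays of date 1 against NP 4, P 3 and P 4 also gave 0 calls. So the 293 calls were not matched by the split that follows date 1. Most splits gave 0 calls, however, so these counts do not exclude a part of scan date. For differences of at least 2-fold, 1 of the 35 splits, the real one, reached 67 calls, and the highest other gave 39. That is a share of 0.0286, the smallest that 35 splits can give, which argues against chance as defined by these splits. The splits ignore scan date and the distance of P 1 and P 2 from the other P arrays, so a first rank is all that they show.

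Rats P 1 and P 2 differed from P 3 and P 4 at 4003 probes, and these pairs were scanned on different dates. If scan date were the whole cause, NP 2 and NP 3 of date 1 would lie with P 1 and P 2. On probes chosen in 1 pair of P arrays and read in the other, their median position was 0.41 (range 0.147 to 0.649), where 0 is the P array of date 3 and 1 that of date 1, which argues against date as the whole cause. They lay higher than NP 4 (median 0.216), so date may account for a part. A test fixed beforehand came out for normalization, since the calls fell to 1 with plain background subtraction and 2 in the authors' values; but all 4003 differences kept their sign in both. The lowest median ratio of their sizes, over these 2, median scaling and cyclic loess, was 1.00 with cyclic loess. It was 1.17 with plain subtraction and 1.17 in the authors' values, where 3549 and 3295 probes were called once the variance prior followed intensity. The offset of 50 in the main values shrinks differences of dim probes, so a ratio above 1 without it carries little weight. Median scaling (ratio 1.01, 5505 calls) and cyclic loess (3515 calls) keep the offset, which argues against the scaling between arrays as the source. The part of the background correction is not settled by these values. Of the 13 marker lists 0 passed camera, but 28 of 146 marker genes were called, and list medians of up to 0.33 remain. So a difference in cell or region makeup, and litter or handling, which the labels do not give, stay open. The pairs also differed as arrays. Median background was 66 on P 3 and 67 on P 4, against 58 on P 1 and 56 on P 2. Median background-subtracted signal was 123.6 and 118.8, against 89.6 and 69.5. Whether this bears on the 4003 probes was not tested.

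Among the called probes, 4 had a second probe for the same transcript (Tmed9, Timm10, Ppp2r2d and an unnamed transcript). If the transcript's level differed between the lines, the second probe would differ too; the highest ratio of its difference to that of the called probe was 0.0664, and each lay below 0.5 of it by more than 2 standard errors, which argues against a change of the whole transcript. Calls of at least 2-fold between the P arrays of both dates had a median ratio of 0.422 over 68 pairs, and drawing as many second probes from them gave ratios as low with a permutation p of 0.0012. A line-specific sequence variant under the called probe, another transcript end or an annotation error of the probe are candidate explanations that these values do not separate. For the other called probes, Bnip3 and Lamp1 among them, no second probe was tested, so the same question stays open.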

How the results depend on the processing

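All 84 called probes kept their sign in every setting where they could be fitted, which for subsets of the arrays follows, in the 82 with 7 values, from groups that do not overlap. Immediate early genes, not called in the main values (median 0.02), passed camera at -0.21 without P 1 and P 2 (adjusted p = 0.00589, and 0.963 with an estimated correlation) and at 0.28 with scan date as a block (0.0336, and 0.978), in opposite directions. The number of calls (84, and 67 at 2-fold) moved by over 1.5 times to 51 in the authors' processed values, 49 and 39 with probes above background on all 7 arrays (fewer probes tested), 151 with array weights, 35 and 27 with a plain test per probe, and 1660 and 165 with scan date as a block. Added after seeing the data, scan date 1 alone gave 1870 and 162, scan date as a random block 159, leaving out P 1 and P 2 189, and leaving out P 3 and P 4 3318 and 179. Leaving out 1 array gave 51 to 121 calls and 48 to 90 at 2-fold, with 51 without NP 4 and 53 without NP 3. Lists past camera, 0 in the main values, were 1 with array weights, 3 with scan date as a block, 2 in scan date 1, 1 without P 1 and P 2, 2 without P 3 and P 4, and 0 to 1 with 1 array left out. With an estimated correlation 0 lists passed in each of these settings. Where not stated, the cause was not tested. Named called probes lost the call in 37 combinations of probe and setting, most often Pard3, Psmb8 and Ppp2r2d, and kept it in 364. In the plain test per probe Fth1, Mmadhc, Cd151, Adprhl1 and the called probes of Tmed9 and Timm10 lost it too. Of 37 probes named for their main values and not called there, 18 were called in some alternative, 9 of them in one chosen before the data were examined: 9 with scan date as a block (Cd302, Golph3l, Pter, Grik5, Cartpt, Camk2b, Cox7a2, Aif1 and Rps3a), 3 with array weights and 1 each without P 2 and P 3. Replicate number as a block gave 104 calls. Same-numbered rats had deviations correlated at 0.10, 0.06 and 0.02, and not every rat correlated best with its own number. With 3 such pairs, these values do not show that the numbers pair rats and cannot exclude it. Plain subtraction gave 61 calls, and 5 of the 84 called probes were not above background on any array of the dimmer line.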

Other observations

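The tests of gene neighbours and of the lists between the P rats were chosen after seeing the data. Between the P rats of scan date 1 and date 3, which the labels do not distinguish, 8 of 20 immediate early genes were called higher in P 1 and P 2 and none was called lower. Junb was higher by 1.14 ± 0.20, Btg2 by 1.13 ± 0.15, Egr3 by 0.85 ± 0.14, Nr4a1 by 0.81 ± 0.15, Arc by 0.76 ± 0.15 and Fos by 0.56 ± 0.15 (list: camera adjusted p = 0.00248, adjusted p = 0.972 with an estimated correlation). Of 31 oxidative phosphorylation genes 10 were called lower and none higher, Uqcrh by -1.90 ± 0.16 and Cox7b by -1.15 ± 0.18 (camera adjusted p = 0.00126, adjusted p = 0.972 with an estimated correlation). Of 33 ribosomal protein genes 12 were called lower and none higher, Rpl4 by -1.13 ± 0.18 (camera adjusted p = 8.78e-07, adjusted p = 0.972 with an estimated correlation). Markers of cell types and regions moved in the same contrast: 28 of 146 were called, 16 higher and 12 lower in P 1 and P 2, in 10 of the 13 lists and in both directions in 5. Slc17a7 (1.52 ± 0.19), Syn1 (1.26 ± 0.18) and Sox10 (1.09 ± 0.16) were higher, and Tspan2 (-1.32 ± 0.15) and Nefm (-1.21 ± 0.15) lower. The astrocyte markers Gfap (0.71 ± 0.14), Aldh1l1 (0.56 ± 0.14) and Glul (0.52 ± 0.15) were called higher and none of that list was called lower. Of all genes tested, 15.5% were called in this contrast, against 19.2% of the markers.

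Lines bred apart carry different haplotypes, so genes that differ between them may lie close together. Of 13 genes with a called probe, 2 pairs lay within 10 annotated genes of each other in the GRCr8 order: Adprhl1 and Lamp1, 5 apart, and Ppp2r2d and Bnip3, neighbours. The Adprhl1 and Lamp1 pair prompted the test, so it was left out. The other 11 genes hold 1 pair, and random draws of 11 tested genes gave as many in 346 of 10000 draws (permutation p = 0.0347). That pair rests on the Ppp2r2d probe whose partner did not follow, and without such calls 8 genes and 0 pairs are left. Whether shared haplotype blocks account for either pair stays open, as pairs are too few and there are no genotypes.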
